A study of Cucumis sativus with 18 samples.

How the data were processed

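RNA from cucumber (Cucumis sativus) ovary tissue was measured in 18 RNA-seq libraries, 3 at each of 6 times of an ovary culture, a tissue culture of unpollinated ovaries that aims at embryos. The groups were taken from the labels: fresh unpollinated ovaries, ovules after 2 days of culture, and embryos after 10, 20, 30 and 60 days of culture. The series design states 3 biological replicates per time. The tissue label reads ovary for every library, while the time label names ovaries, ovules or embryos, so what was sampled changed with time from the fresh ovaries to day 2 and from day 2 to day 10. The labels name no growth conditions, sequencing batch, date or donor plant.

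Per the labels' protocols, RNA was extracted with Trizol, treated with DNase, poly(A) selected, fragmented and sequenced paired-end on an Illumina HiSeq instrument. The extraction text also names an adipose type, which a plant has none of, so part of it may come from another study and the steps are given as stated. Per the submitters' processing notes, TopHat2, TopHat and HTSeq version 0.6.1p2 were used, with no role, order or setting given. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The values the authors deposited are RPKM (reads per kilobase of gene per M reads, where M stands for mega), per the file headers, with 1 column per library and 23248 genes per time. The header of the fresh ovaries holds its 3 library names in 1 cell, and its columns were taken in the order of those names. RPKM corrects for depth and for gene length within a library but not for a change in the make-up of the RNA, so a few very abundant transcripts can shift all other genes.

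RPKM values are not counts, so the test fixed before the data were examined for that case was used in place of the count test planned first. limma version 3.58.1 in R 4.3.3 was run on log2(RPKM + 1), with a trended and robust empirical Bayes variance. Genes with an RPKM of at least 1 in 3 or more libraries were tested, which left 18153 genes. All 18 libraries entered 1 model with 1 coefficient per time and shared 1 estimate of the spread. The 5 consecutive times were compared, and an F test asked which genes varied over the 6 times. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Means and SDs of single genes are of the RPKM values over 3 libraries. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

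Depth was worked out from the values. An RPKM is a whole number of reads divided by the gene's length and the library's total, so low genes step in multiples of 1 read. Of 1200 low genes, 1189 had values that were whole multiples of 1 step within a tolerance of 0.02. From these steps the library totals, and from the totals a length in whole bases, were obtained for 21758 of the 21761 genes above 0. Every RPKM above 0 in those genes came within 0.1 of a whole read. The reads summed over genes to between 99.97% and 99.99% of the totals, so the totals are those of reads assigned to genes. The recovery was tested on 12 simulated sets with known reads and lengths. The first version solved 5 of these 12, because it could set a library's total wrong by a whole factor. A check for a factor shared by all reads of a library was then added, together with a longer search for the length scale. The version used solved all 12, with the simulated reads of 99.91% to 99.98% of genes returned in every library. In the deposited data the added check changed 0 library totals. The depth was 21.8 to 34.0 M reads in the replicate 1 and 2 libraries and 48.9 to 72.5 M reads in the replicate 3 libraries. At each time the replicate 3 library was the deepest. Genes at an even number of reads, from 6 to 40, were 0.99 to 1.18 times as many as the mean at the neighbouring odd numbers, and over 1 times in 16 of the 18 libraries. Whether both mates of some pairs were counted as separate reads was not settled, so the depth may count reads rather than fragments. The median recovered length was 2902 bases over 18988 genes with at least 200 reads, and the median gene span of protein-coding genes in the RefSeq table, of another assembly or annotation, was 3386.5 bases. Whether the authors' length includes introns is not given in the sources used here. It changes the RPKM level of a gene but not its ratio between times. Reads without molecular identifiers are not independent molecules, so read numbers overstate the precision.

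The test was run on simulated reads drawn from the real mean levels and depths, with 200 genes changed at 1 step. For the step from fresh ovaries to day 2, with 17698 genes tested, 16 of 66 genes changed 1.5-fold, 40 of 64 changed 2-fold and 53 of 60 changed 4-fold were called, all in the right direction, and 6.84% of the calls were false. For the step from day 10 to day 20, with 17719 genes tested, 15 of 64, 45 of 67 and 60 of 66 were called, and 4.76% of the calls were false. The real steps called 5617 to 11517 genes, far more than the 200 changed here. The simulated libraries were also drawn independently, with no deviation shared between times and no change in the make-up of the RNA. These shares therefore do not carry over to the real steps.

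Of the 23248 gene IDs, all as the files give them, 0 matched the RefSeq gene table of assembly Cucumber_9930_V3 by ID, locus tag, synonym or accession. The files do not pair the IDs with names. The 40 gene lists fixed before the data were examined, among them heat shock proteins, histones and embryogenesis regulators, are defined by product descriptions, so 0 lists could be tested and no gene is named by function. For each comparison the 2 genes with the highest and the 2 with the lowest log2 fold change are given, among called genes with a mean RPKM of at least 5 over both times and no overlap between the libraries of the 2 times, as fixed before the data were examined.

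The replicate numbers recur at every time. Libraries with the same number deviated together from their group means, with correlations across genes over 0.1 in all 3 pairs for 4 of the 5 comparisons, the exception being day 2 to day 10. Over all times 43 of 45 such pairs were over 0.1, with a range of 0.07 to 0.65, and 18 of 18 libraries correlated best with their own number. Pairs of different numbers ranged from -0.47 to 0.26. Only replicate 3, at 0.48 to 0.65, stood above that range in all of its pairs. Deviations from a mean of 3 libraries sum to 0, so a deviation shared by replicate 3 alone can also raise the values of replicates 1 and 2. The pairing rests on these values, since the labels do not say what a number stands for. The fit without the number as a block was fixed as the main one before the data were examined, and the blocked fit is an alternative.

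The alternatives were median-ratio and upper quartile scaling of the RPKM values, a pseudocount of 0.1, no filter, a filter on recovered reads, the replicate block, only the 6 libraries compared, a test against a 2-fold change, and leaving out each library in turn. Added after the data were seen were limma's voom on the recovered reads, a batch term for the replicate 3 libraries, only replicates 1 and 2, and leaving out the replicate 1 libraries of day 10 and day 20.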

Results

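Gene expression was followed through ovary culture of cucumber, in which unpollinated ovaries are placed on medium so that embryos form without fertilisation. Fresh ovaries, ovules after 2 days and embryos after 10, 20, 30 and 60 days were each sampled in 3 libraries. The 18 libraries held between 21.8 and 72.5 M (mega) reads assigned to genes. Libraries of the same time correlated across genes at r of 0.957 to 0.991, on log2(RPKM + 1). Changes between consecutive times were asked for 18153 genes with the limma test, with adjusted p-values after Benjamini and Hochberg. The files do not pair gene IDs with names, so genes are given by ID.

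Expression varied over the culture for most genes. Of the 18153 genes tested, 16702 varied over the 6 times, which is 92.0%. The mean was highest in fresh ovaries for 3970 of these genes, at day 2 for 3100, at day 10 for 1755, at day 20 for 1713, at day 30 for 2661 and at day 60 for 3503. The mean was lowest in fresh ovaries for 4209 genes, at day 10 for 3545 and at day 30 for 918. The counts of day 10, day 20 and day 30 depend on the scaling. Day 30 held the lowest mean of 1621 genes and the highest of 1689 under median-ratio scaling, and 1276 and 2028 under upper quartile scaling. Under median-ratio scaling day 10 and day 20 held the highest mean of 2326 and 2251 genes, more than day 30. Under upper quartile scaling they held 1872 and 1997, fewer than day 30. The lowest mean was at day 20 for 2915 genes as deposited and for 1710 under median-ratio scaling. Few genes were restricted to 1 time under a strict rule, and no other ceiling was tried. Low levels at other times fail it, as for Csa5G165870, at 63.2 RPKM at day 2 and 1.23 at day 30. With an RPKM of at least 1 in the 3 libraries of a time and under 0.1 in the other 15, there were 2 genes for fresh ovaries, 1 for day 2 and 0 for each later time.

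**Figure D1:**
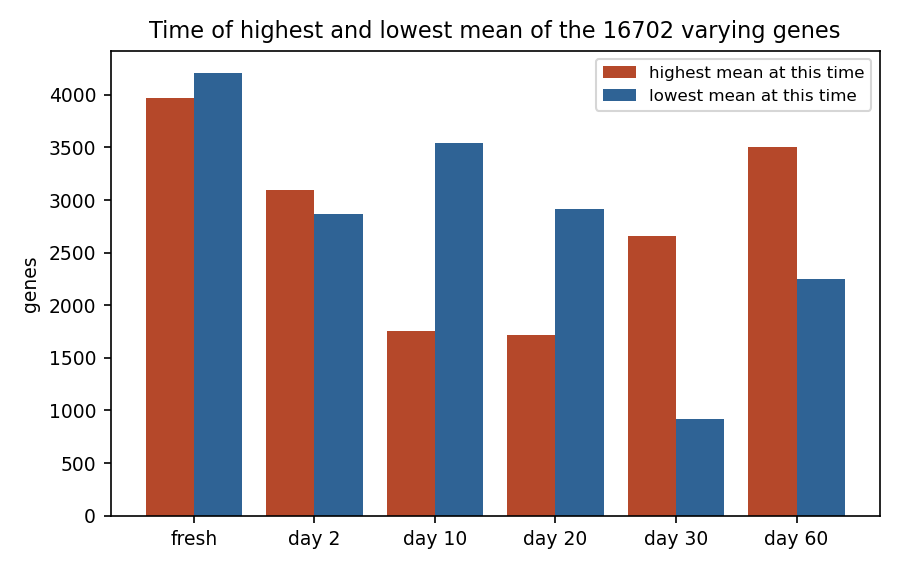
Number of genes (vertical axis) with their highest mean (red bars) and lowest mean (blue bars) of log2(RPKM + 1) at each of the 6 times (horizontal axis), among the 16702 genes that varied. Fresh ovaries held the highest mean of 3970 genes and the lowest of 4209, while day 30 held the lowest of 918, or of 1621 under median-ratio scaling.

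The distance between times, as the root mean square difference of mean log2(RPKM + 1) over the tested genes with the variance from replicate noise subtracted, was largest from fresh ovaries to day 10 and day 20 and smaller to later times. Fresh ovaries lay 1.11 from day 2, 1.23 from day 10, 1.22 from day 20, 1.08 from day 30 and 0.96 from day 60. Leaving out 1 library at a time gave 1.21 to 1.24 for fresh ovaries against day 10 and 0.95 to 0.97 against day 60, and these distances were 1.23 and 0.95 under median-ratio scaling. The closest times were day 10 and day 20, at 0.57, followed by day 30 and day 60, at 0.67.

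**Figure D2:**
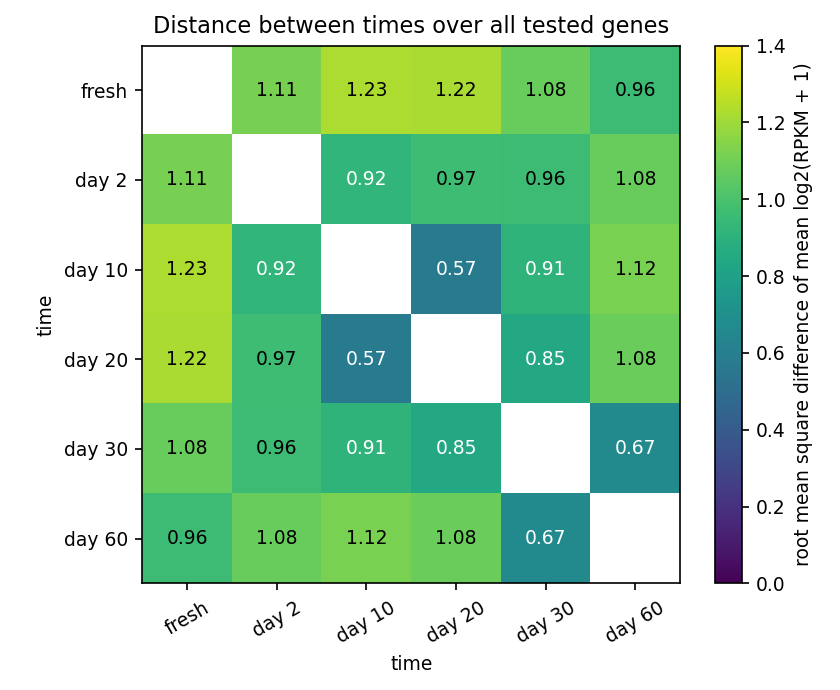
Root mean square difference of mean log2(RPKM + 1) between each pair of the 6 times over all tested genes, with the variance from replicate noise subtracted, as colour and as a printed value, each mean over 3 libraries. The smallest distances are 0.57 between day 10 and day 20 and 0.67 between day 30 and day 60, and fresh ovaries lie nearer to day 60, at 0.96, than to any other time.

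The first comparison asked what changed between fresh ovaries and ovules cultured for 2 days. Csa4G000860 rose from an RPKM of 2.10 ± 1.90 in fresh ovaries to 7471 ± 613 at day 2 (SD, n = 3 each), and was still at 1471 at day 10 and at 72.6 at day 60. Csa2G021500 rose from 1.34 ± 0.913 to 2683 ± 220. CsaUNG012530 fell from 128 ± 40.6 to 0.401 ± 0.359, on 15 reads in the 3 day 2 libraries together, and Csa7G372360 fell from 217 ± 49.7 to 2.42 ± 0.567. In all, 11517 genes changed, 5650 higher and 5867 lower at day 2, the largest count of the 5 steps. Which direction was more frequent depends on the scaling, with 6079 higher and 5393 lower under upper quartile scaling. A change of at least 2-fold was seen in 2387 of the genes that rose and 2432 of those that fell. The log2 fold change of Csa4G000860 was 11.48 (SE 0.37, adjusted p = 5.54e-13), or 10.85 without replicate 2 of the fresh ovaries, which held 1 read of this gene against 37 and 47, and that of CsaUNG012530 was -6.51 (SE 0.62, adjusted p = 1.79e-07). The libraries of the 2 times did not overlap for 69.3% of genes, where chance gives 10%. Tested against a 2-fold change, 2376 genes passed.

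**Figure D3:**
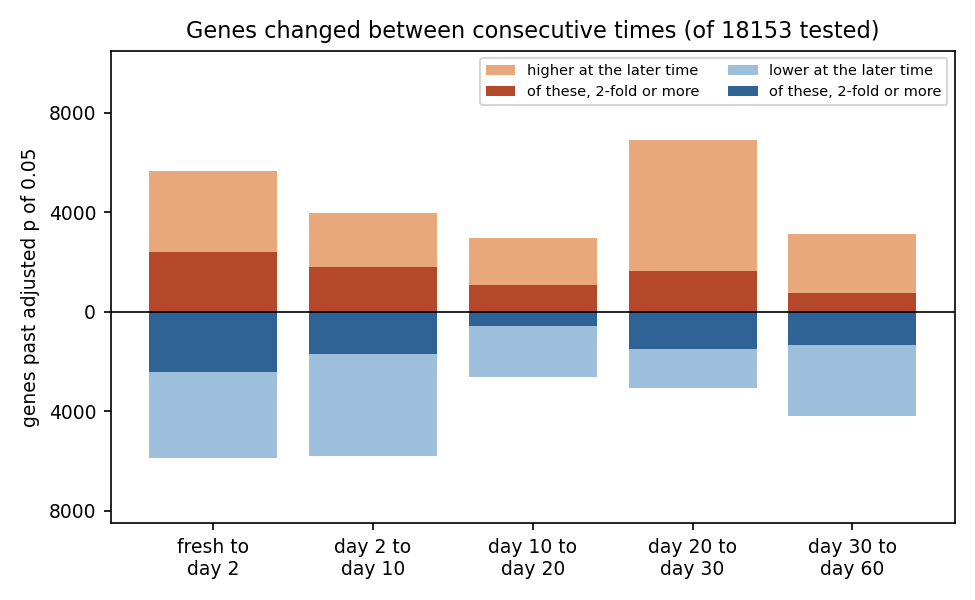
Genes past an adjusted p of 0.05 in limma (vertical axis) for each step between consecutive times (horizontal axis), with genes higher at the later time above 0 and genes lower below it, and the part with a change of at least 2-fold in dark colour. The step from fresh ovaries to day 2 changed 11517 genes and the step from day 10 to day 20 changed 5617. The 6923 genes higher at day 30 than at day 20 fall to 4114 under median-ratio scaling.

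The second comparison set embryos at day 10 against ovules at day 2, so that, as at the first step, the sampled tissue and the time changed together. Csa7G037530 rose from 0.293 ± 0.313 RPKM at day 2 to 1353 ± 455 at day 10 (SD, n = 3 each) and stayed at 1298 at day 20 and 937 at day 30. Csa6G085120 rose from 0.488 ± 0.272 to 594 ± 159. Csa7G073510, at 88.0 ± 8.20 at day 2, fell to 0.432 ± 0.406, and Csa5G165870 fell from 63.2 ± 1.57 to 0.475 ± 0.431. Each of the last pair had its highest mean of the 6 times at day 2, with 0.438 and 0 RPKM in fresh ovaries. The number of changed genes was 9773, of which 3983 were higher and 5790 lower at day 10, and 1806 and 1705 of these changed at least 2-fold. Csa7G037530 had a log2 fold change of 10.01 (SE 0.25, adjusted p = 7.61e-14) and Csa5G165870 one of -5.49 (SE 0.16, adjusted p = 3.44e-13). Among genes that passed the test against a 2-fold change, 1627 in all, 59.6% were higher at day 10, against 40.8% of all changed genes. The median log2 fold change over all tested genes was -0.11 at this step, and -0.02 under median-ratio scaling, which gave 4644 genes higher and 4828 lower. Upper quartile scaling gave 3973 and 5844, so the excess of falls among all changed genes depends on the scaling.

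Many genes that changed at 1 step changed back at the next, at day 2, day 10 and day 20 alike. Of the 5650 genes that rose from fresh ovaries to day 2, 2803 fell by day 10, where independent lists would share 1802. Of the 5867 that fell by day 2, 1935 rose by day 10, where independent lists would share 1287. The log2 fold changes of the 2 steps had a covariance across genes of -0.313, against a mean of -0.020 and a lowest value of -0.054 in 20 simulated sets with no effect. At day 10, 1340 genes rose and then fell, where independent lists would share 578, and at day 20 1315 did, where they would share 505, with covariances of -0.155 and -0.147. In the simulated sets these 2 covariances had means of -0.021 and -0.020 and lowest values of -0.057 and -0.038. Also at day 10, 734 genes rose at both steps, against 655 of independent lists, and 469 fell at both, against 840. At day 30 the covariance, -0.011, lay within the range of the simulated sets. The lists there overlapped more than independent ones both ways. Of the genes that changed back, 1976 rose and then fell, against 1599, and 642 fell and then rose, against 527. Those that fell at both steps numbered 913, against 709, and those that rose at both 1226, against 1188. Each pair of comparisons shares the libraries of the time between, so part of the excess may come from these. The mean of that time also enters the 2 fold changes with opposite signs. Levels that differ between times with no tendency to return would thus give a negative covariance too. Neither independent lists nor the simulated sets, which hold no difference between times, show that part. An excess of changing back over unrelated levels was therefore not shown.

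The third comparison, day 20 against day 10, gave the fewest changes. Csa1G043220 rose from 2.85 ± 1.47 to 221 ± 31.8 RPKM and Csa5G649870 from 3.42 ± 1.33 to 192 ± 11.6 (SD, n = 3 each). Csa6G017030 fell from 214 ± 29.5 to 6.59 ± 0.506 and Csa1G002090 from 191 ± 23.2 to 8.09 ± 1.72. Changes reached 5617 genes, 2983 higher and 2634 lower at day 20, and 1069 and 575 of them changed at least 2-fold. The log2 fold change was 5.91 for Csa1G043220 (SE 0.26, adjusted p = 1.33e-10) and -4.82 for Csa6G017030 (SE 0.15, adjusted p = 9.85e-12). The libraries did not overlap for 36.0% of genes, where chance gives 10%. Fitted on the 6 libraries of day 10 and day 20 alone, 3113 genes changed. In that limma fit the adjusted p was 8.86e-05 for Csa1G043220 and 6.85e-05 for Csa6G017030. Fewer libraries estimate the spread there, and libraries of the same time correlated least at day 10 and day 20, down to 0.957 and 0.958. The spread shared by all times may thus understate that of this step. In the fit on all 18 libraries, 527 genes passed against a 2-fold change, 65.1% of them higher at day 20. The replicate 1 libraries of day 10 and day 20 list fewer genes above 0, 17653 and 18591, than the other 16.

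The fourth comparison set day 30 against day 20. CsaUNG012530, which had fallen by day 2, rose from 2.32 ± 2.44 to 158 ± 61.2 RPKM, and Csa3G535100 rose from 0.397 ± 0.213 to 23.8 ± 2.36 (SD, n = 3 each). Csa2G023890 fell from 628 ± 212 to 0.656 ± 0.821, and Csa1G043220, which had risen by day 20, fell from 221 ± 31.8 to 1.19 ± 0.689. The test called 9994 genes, 6923 higher and 3071 lower at day 30, with 1654 and 1491 of these changed at least 2-fold. Csa2G023890 had a log2 fold change of -8.62 (SE 0.34, adjusted p = 1.86e-11) and Csa3G535100 one of 4.16 (SE 0.13, adjusted p = 2.41e-12). That of CsaUNG012530 was 5.85, and 5.15 without replicate 1 of day 20, which held 0 reads of it against 22 and 104 and lists fewer genes than most libraries. The share of changed genes that were higher, 69.3%, went with a median log2 fold change of 0.24 over all tested genes. That share was 48.8% under median-ratio scaling, 59.0% under upper quartile scaling and 34.2% among the 1258 genes past a 2-fold change, so the balance of rises and falls at this step depends on the scaling and on the size of change asked for.

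**Figure D4:**
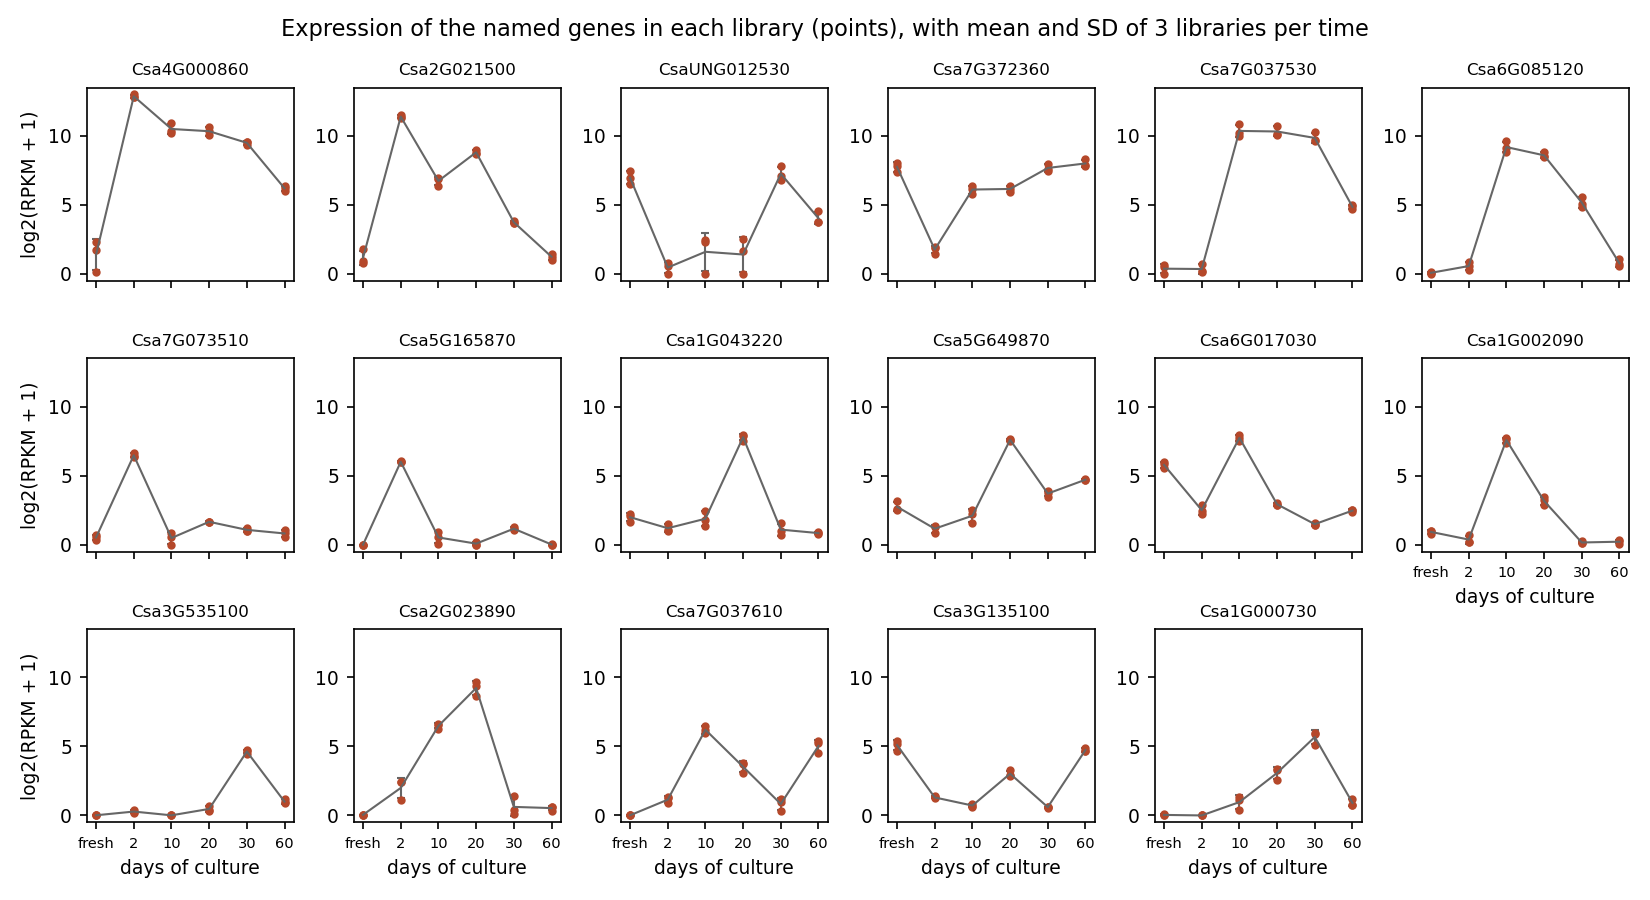
Expression as log2(RPKM + 1) (vertical axes) in each library (red points) against days of culture, evenly spaced (horizontal axes), for the 17 named genes, with grey lines for the mean and bars for the SD of 3 libraries. Csa1G043220 stands at a mean of 221 RPKM at day 20 and at 3.01 or less at the other times, while Csa7G037530 stays between 937 and 1353 from day 10 to day 30.

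The fifth comparison set day 60 against day 30. Csa7G037610 rose from 0.837 ± 0.534 to 32.8 ± 9.44 RPKM and Csa3G135100 from 0.518 ± 0.0437 to 25.9 ± 2.77 (SD, n = 3 each). The level of Csa3G135100 at day 60 came near that of fresh ovaries, 34.0. Csa7G037530, which had risen by day 10, fell from 937 ± 239 to 27.9 ± 3.18, and Csa1G000730 fell from 52.3 ± 16.1 to 0.902 ± 0.355. Between these times 7307 genes changed, 3114 higher and 4193 lower at day 60, with 753 and 1320 of them changed at least 2-fold. The log2 fold change of Csa3G135100 was 4.14 (SE 0.15, adjusted p = 2.88e-11) and that of Csa7G037530 was -5.00 (SE 0.25, adjusted p = 9.17e-10). Against a 2-fold change 620 genes passed, 25.2% of them higher at day 60, compared with 42.6% of all changed genes. The excess of falls among all changed genes depends on the scaling, with 3576 higher and 3612 lower under median-ratio scaling and 3601 and 3656 under upper quartile scaling.

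Of the 6 pairs of steps with no library in common, 2 showed the strongest opposition of early and late changes by correlation across genes: fresh ovaries to day 2 with day 30 to day 60, and day 2 to day 10 with day 20 to day 30. Of the 5650 genes that rose from fresh ovaries to day 2, 2073 fell from day 30 to day 60, 1.59 times the 1305 that independent lists would share. Of the 5867 that fell at the first step, 1673 rose at the last, 1.66 times the 1006 of independent lists. Genes that rose at both steps numbered 590, 0.61 times those of independent lists. Across genes, which are not independent replicates, the log2 fold changes of the 2 steps correlated at a Pearson r of -0.30 and a Spearman rho of -0.31. Likewise, 1518 genes rose from day 2 to day 10 and fell from day 20 to day 30, 2.25 times the 674 of independent lists, and 3134 fell at the former step and rose at the latter, 1.42 times the 2208 of independent lists. These 4 ratios were 1.62, 1.64, 1.92 and 1.62 under median-ratio scaling. This pair had a Pearson r of -0.31 and a rho of -0.28. Day 10 and day 20 lie close, at a distance of 0.57, and their levels enter the 2 fold changes of this pair with opposite signs. Levels that differ between times with no tendency to return would thus give opposed changes here too. Day 2 lay 0.96 from day 30 and 0.92 from day 10, so a return to the levels of day 2 was not shown. In the other 4 pairs r lay between -0.17 and -0.02 and rho between -0.09 and 0.07. Opposed changes were still in excess in some lists of these 4 pairs, as in the 1419 genes that rose from day 2 to day 10 and fell from day 30 to day 60, against 920 of independent lists. For day 10 to day 20 with day 30 to day 60 the excess went both ways, with 716 genes that rose at both against 512, 821 that fell at both against 608, and 921 that rose and then fell against 689.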

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

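The alternatives were fixed before the data were examined, except voom, the batch term, the fits on replicates 1 and 2 and the fit without 2 libraries, which were chosen afterwards. All 360 alternatives of the named genes kept their direction and stayed past the threshold, and 279 of 298 alternatives of counts stayed within 1.5 times. The named genes were picked from these data for the largest changes among called genes. Their stability was therefore nearly fixed by the choice and does not carry over to other genes. Tested against a 2-fold change, the 5 steps in order gave 2376, 1627, 527, 1258 and 620 genes, fewer by construction. With only the 6 libraries of its own times each step gave 11578, 7949, 3113, 9171 and 8736 genes. Leaving out 1 library gave 10568 to 11141, 8843 to 9489, 4807 to 5393, 8975 to 9561 and 5951 to 6481 genes, with the 2 libraries left at that time assumed to vary like those of the other times. With the replicate block the counts were 12724, 11158, 7289, 11600 and 9224, and the pairing ended no call of a named gene. Voom on the recovered reads gave 11457, 9601, 5523, 10207 and 7754 genes, and the batch term for replicate 3 gave 12414, 10828, 6827, 11191 and 8751. Replicates 1 and 2 alone gave 10171, 8458, 4123, 8412 and 5395, and leaving out replicate 1 of day 10 and day 20 gave 12491, 10124, 5004, 10263 and 8749. Median-ratio scaling moved the genes higher at day 30 than at day 20 from 6923 to 4114, and the median log2 fold change of all genes there from 0.24 to 0.02. The count tests and the tests of gene lists planned first were not run, because the values are RPKM and no ID matched a description. Depth limits low genes, since 1 RPKM of a short gene rests on few reads, and it is greater in the replicate 3 libraries.

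Other splits of the 6 libraries of each comparison into 3 and 3 make 10 splits, so no share under 0.05 is possible. Of these 10, only 1, the real split, gave as many genes at each step, with at most 0, 1, 22, 0 and 0 genes from the other splits against 11517, 9773, 5617, 9994 and 7307. For variation over the 6 times, 1 of 100 splits, the real one, reached 16702 genes, and the highest of the others gave 415, so random labelling of the libraries is argued against there. The other splits mix libraries of different times in a group, so the differences between times enter the spread and few calls were likely. Their counts are thus no rate of false calls. The splits treat the libraries as exchangeable, although those with the same number deviated together. They cannot separate time from anything else that changed with it, such as what was sampled. These tests were chosen with the counts known.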

Other observations

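The patterns weighed here were noticed in the data. The tests of their explanations were set down before the values they measure were seen, except that pairs 2, 5 and 10 IDs apart, and the lengths of pairs over 1 ID apart, were considered afterwards.

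Genes with successive IDs changed together: from fresh ovaries to day 2, 926 pairs of successive IDs changed at least 2-fold the same way, 1.45 times the mean of 200 shuffled orders, and the ratio was 1.77, 2.52, 1.99 and 2.15 at the later steps. Only tested genes were ordered by ID, so successive IDs, and those given as further apart, can have untested genes between them. Reads shared between near-identical copies would favour genes of like length. Such pairs had ratios of 1.69, 2.29, 3.34, 2.60 and 3.41 at the 5 steps against 1.34, 1.55, 2.14, 1.73 and 1.68 for lengths over 1.5 times apart, so copies may give part of the excess. At the first step 612 pairs of unlike length, 1.345 times the shuffled mean, stood against at most 507 in a shuffle, so copies of like length alone do not give all of it. The split by length cannot exclude copies of unlike length, since no sequences were compared. Overlap of adjacent gene models would join direct neighbours only, and as the sole cause at the first step it is argued against by pairs 3 IDs apart, 695 against at most 687 in a shuffle or 1.088 times, and by those 2 and 5 apart, 748 against at most 687 and 711 against at most 689, while at the 4 later steps pairs 2 apart passed the highest shuffle at all 4, pairs 3 apart at 2 and pairs 5 apart at 0, and pairs 10 apart passed it at 0 of the 5 steps. Overlap and copies together may still account for much of this. At the first step the pairs 3 apart above the highest shuffle were those of like length, 217 against at most 212. From day 10 to day 20, pairs 3 apart of unlike length passed it too. Pairs of unlike length over 1 ID apart passed the highest shuffle, narrowly, in 6 of 20 counts over the 5 steps. Whether overlap and copies together suffice therefore stays open. Local co-regulation stays open as an untested hypothesis, and whether the order of IDs follows the chromosome is not given in the sources used here.

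The replicate 3 libraries deviated together from their group means at all 6 times. Over 7571 genes with a mean RPKM of at least 10, the median correlation across genes of the 15 pairs of these libraries was 0.706, and 43.7% of genes lay on 1 side of the group mean in all 6 of them, where chance gives 3.1%. Unequal read numbers do not account for this among these genes, since thinning every library to 20 M reads left a median of 0.682. Genes at this level keep many reads after thinning, so a large fall was unlikely from the start, and lower genes were not tested. Gene length as the sole cause is argued against by a median of 0.697 after a trend on the recovered length was removed. A part of gene length stays open, since the mean deviation of replicate 3 had a Spearman rho of 0.17 with log length across genes. The recovered length may also differ from that of the transcripts. A shared culture, plant or library batch could give such a pattern, but the labels name none and it was not tested, nor was any biological explanation. It adds to the spread within each time, so with a batch term for replicate 3 the calls rose, to 6827 from 5617 for day 10 against day 20.

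The replicate 1 libraries of day 10 and day 20 list fewer genes than the other 16. Depth does not account for it, since at 20 M reads they list 17649 and 18578 genes against at least 19046, though with at least 5 reads day 20 replicate 1 lists 18371, inside the 18204 to 18839 of the other 16, so its shortfall lies among genes with 1 to 4 reads, while day 10 replicate 1 lists 17541. Nor do a few abundant genes account for it, with at most 18573 against at least 19003 at 15 M reads once each library's top 100 genes were left out. Time in culture as the sole cause is argued against by the numbers listed. Only 1 of the other 4 libraries of day 10 and day 20, replicate 2 of day 10 at 19046, fell below the 12 libraries of other times. A part of time in culture stays open, since genes expected at 20 to 200 reads and at 0 were more frequent at these times. They numbered 58 and 27 in replicates 2 and 3 of day 10 and 16 and 27 in those of day 20. In the 12 libraries of other times they numbered at most 11. Few starting molecules copied many times may be the cause, since at 20 M reads only 108 and 207 genes had 1 to 4 reads against 747 to 1311 elsewhere, and 350 and 200 genes expected at 20 to 200 reads had 0 against at most 58, values seen before that explanation was written. Its own test stayed undecided, because the squared deviation over expected reads had a median of at least 13.47 in these 2 libraries but reached 15.7 in replicate 3 of day 10, whose expected reads come partly from replicate 1 of that time.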
